A study of Mus musculus with 5 samples.

How the data were processed

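RNA was measured in 5 libraries: E14 mouse ESCs in LIF with serum, E14 ESCs in LIF with BMP-4 in a basal medium, untreated EpiSCs derived from ESCs, and such EpiSCs treated with BMP-4 over 1.5 h and over 24 h. Per the labels' protocols, ESCs grew on gelatin, and EpiSCs grew in N2B27 medium with FGF2 and Activin A on plates coated with serum. Poly(A) RNA was selected with oligo-dT, fragmented and made into directional libraries with a small RNA kit. Each group held 1 library, so no p-value was computed for a difference between libraries. No paired analysis was possible because each group held 1 library.

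The deposited values are FPKM per gene, made by the authors with TopHat and Cufflinks on the mm9 build, per the submitters' processing notes, which also name Picard and SAMtools. Per the file headers, each FPKM comes with a lower and an upper confidence bound and a status, and the bounds are 95% limits by the definition of Cufflinks. The annotation, the filters and the way libraries were scaled to each other are not given in the sources used here. The table held 23951 genes with unique symbols. A status other than OK occurred in at least 1 library for 8 genes, 6 of them with a mean of at least 1 FPKM, and such a gene was left out of any comparison that used that library. An exact 0 can be a failed estimate, because Hmgcs1, a widely expressed gene of the cholesterol pathway that was picked after its values were seen, is listed at 0 in all libraries, so a gene named at 0 in a library is described as listed at 0, with no fold against it. Such genes still enter counts and list medians through FPKM + 1. Gene positions are those of the file, written from 1: the file counts starts from 0, as 8129 of 22460 symbols matched in a RefSeq table had the same span under that reading and 515 under the other. Cufflinks positions are spans of a locus and can hold several genes.

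Depth was estimated because FPKM values hide it. Below 0.5 FPKM the most frequent ratio of a gene's values between libraries gives the relative worth of 1 read, which was 1.57, 1.5, 1.36 and 1.22 times that of the 24 h library for the ESCs in LIF and serum, the ESCs in LIF and BMP-4, the untreated EpiSCs and the 1.5 h library. The scale came from genes with 1 transcript longer than 1500 nt in GENCODE M21. Of 1169 such low genes, 368 (31.5%) had values at whole multiples of 1 read, within 0.03, and the mode of 233 of them set the total, so the totals are approximate. The deepest library was the 24 h library. Deposited intervals were wide: in ESCs in LIF and serum the median distance from the value to its upper bound was 111% of the value at 1 to 5 FPKM, 75% at 5 to 20, 57.8% at 20 to 100 and 45.7% at 100 to 1000. How these intervals were modelled is not given in the sources used here. Without replicates they are no measured spread between cultures.

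For each of 6 comparisons the difference of log2(FPKM + 1) was taken over genes with a mean of at least 1 FPKM over the 5 libraries, and genes at least 2-fold apart were counted. Unless the text says that a gene or its list was chosen after the values were seen, named genes follow a rule fixed before the data were examined, as were 33 gene lists of 474 genes, all found in the table by symbol and 336 with a mean of at least 1 FPKM. The list of Hox genes had 0 members at that mean and so enters no comparison. A gene near 0 in ESCs or in EpiSCs passes that mean through the other cell type, which favours differences between cell types in list counts. In the same way a gene low in the other libraries can pass through a library with BMP-4, which favours higher genes there. The rule took up to 12 higher and 12 lower genes per comparison that were at least 2-fold apart, reached 5 FPKM in 1 library, had intervals apart and were neither small RNAs nor predicted genes. It also took up to 4 higher and 4 lower members of each list described, all BMP targets in the table, and Klf2, Klf4, Klf5, Pou5f1, Sox2 and Nanog. Not every gene the rule allows is printed. A list's median was placed among the medians of 10000 random lists of the same size matched on 20 bins of mean expression, as a description of these libraries and not a test. Lists of imprinted genes, of anterior streak and organizer genes and of posterior streak genes were chosen after the data were seen. Counts of shared genes are set beside the product of the list sizes over the genes compared. For the comparisons that share the untreated EpiSC library, 200 sets of unchanged libraries were simulated, from the deposited intervals and from Poisson read counting at the estimated depth.

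Read counting alone, simulated 100 times for an unchanged pair, gave at most 24 genes 2-fold apart for the ESC comparison (428 observed), 19 and 20 for EpiSCs against ESCs (2323 and 2313), 13 for 1.5 h (46), 10 for 24 h (130) and 9 for 24 h against 1.5 h (114). These numbers rest on the estimated depth and on annotated transcript lengths. They leave out variation from library preparation, read assignment and culture, so a count above them is not shown to be a response. Of the 46 genes at 1.5 h, 24 were small RNAs. Without small RNAs and predicted genes 13 higher and 6 lower genes remained. Tested on simulated data with 10889 genes for the 1.5 h comparison, the counting step recovered 90% of 100 genes changed 3-fold and 100% of 100 genes changed 8-fold, and a list of 15 genes shifted by 0.5 reached percentile 100.0.

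Shared sequence was checked with minimap2 2.31: 10 of 209 named genes (201 with a sequence) matched a transcript of another gene at 95% identity over at least 50% of their length. They were Bnip3, Dppa5a, Hspb1, Pgk1, Pisd-ps1, Rpl10l, S100a4, Tdh, Tuba3a and Zscan4f, and their FPKM are uncertain to that extent. The limit on length misses genes longer than their match: Eif3j1 was covered over 43.8% of its 5413 nt by Eif3j2 at 99.4% identity, while Eif3j2 was covered over 100% by Eif3j1. Alternatives were a pseudocount of 0.1 or 5, no filter, a mean of at least 5 FPKM, rescaling by median ratio or by upper quartile, intervals apart, and, added after the data were seen, the exclusion of small RNAs and predicted genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.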

Results

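Gene expression was measured by RNA sequencing in mouse embryonic stem cells (ESCs) of the E14 line and in epiblast stem cells derived from ESCs (EpiSCs), which stand for the naive and the primed state of pluripotency. The question set by the study was how bone morphogenetic protein (BMP) signalling acts in each state. The 5 libraries fell into 5 groups of 1 library: ESCs kept with leukaemia inhibitory factor (LIF) and serum, ESCs kept with LIF and BMP-4 at 10 ng/ml in basal medium, untreated EpiSCs kept with FGF2 and Activin A, and EpiSCs given BMP-4 at 10 ng/ml for 1.5 h or 24 h. No group had a replicate, so no difference below was tested against a spread between replicates and no p-value is given for a difference between libraries. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds are ratios of FPKM + 1. "Higher" or "lower" in a count means at least 2-fold on that scale. Of 23951 genes, 11011 had a mean of at least 1 FPKM over the libraries. Between 10478 and 10779 genes per library reached 1 FPKM. The depth, estimated from whole-read steps in low values, was about 8.46 M reads (M, the mega prefix) for ESCs in LIF and serum, 8.88 M for ESCs in LIF and BMP-4, 9.77 M for untreated EpiSCs, 10.9 M after 1.5 h and 13.3 M after 24 h. Ranges in parentheses after an FPKM value are the interval deposited with it.

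Untreated EpiSCs were compared with ESCs in LIF and serum to describe the naive and the primed state. The naive pluripotency genes were far lower in EpiSCs: all 20 of 20 listed genes were lower, with a median log2 difference of -4.89. Zfp42 (Rex1, a marker of naive cells; mm9 chromosome 8, 44380421 to 44392363) stood at 1336 FPKM (882 to 1790) in ESCs and at 0.531 (0 to 1.62) in EpiSCs. Esrrb, a nuclear receptor of the naive network, stood at 132 and 0.706 FPKM, and Nr0b1 at 103 FPKM in ESCs while it was listed at 0 in EpiSCs. Primed epiblast genes were higher in EpiSCs in 16 of 19 cases (median 2.67). Fgf5, a growth factor gene of the postimplantation epiblast (chromosome 5, 98683203 to 98706052), stood at 0.0495 FPKM in ESCs and 133 (73.7 to 192) in EpiSCs.

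Genes of pluripotency shared by both states differed less, with 5 of 13 lower in EpiSCs and 0 higher (median -0.76). Pou5f1 (Oct4) stood at 1677 FPKM (1102 to 2252) in ESCs and 1264 (809 to 1718) in EpiSCs. Sox2 was 2.43-fold lower in EpiSCs and Nanog, which is on the naive list, 2.73-fold lower, with overlapping intervals for both in this comparison. Of the Kruppel-like factors, 7 of 14 were lower in EpiSCs (median -0.98), led by Klf2 (125 and 2.28 FPKM), Klf4 (22.1 and 0.497 FPKM) and Klf5 (45.7 and 6.07 FPKM). Responders to LIF and STAT3 were lower in 10 of 13 cases and higher in 1 (median -2.33), with Tfcp2l1 at 40.7 and 0.29 FPKM.

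Of the primitive streak and early mesoderm genes, 12 of 15 were higher in untreated EpiSCs than in ESCs in LIF and serum and 1, Fgf17, was lower (median 2.55), among them Fgf8 (0.272 and 61.2 FPKM), Gsc (0.9 and 36.0 FPKM) and Eomes (0.681 and 23.9 FPKM). Of the Nodal and Activin targets, 8 of 14 were higher and 6 lay within 2-fold (median 1.39). Lefty1, a Nodal antagonist, stood at 3.35 and 70 FPKM, and Cer1, a secreted BMP and Nodal antagonist, was listed at 0 in ESCs and stood at 35 FPKM in EpiSCs. Genes of the serum and SRF response were higher in 12 of 14 cases (median 2.61), including the contractile genes Tpm1 (71.9 and 773 FPKM) and Cnn1 (0.305 and 10.5 FPKM). The EpiSC medium held no serum, unlike that of these ESCs, though the EpiSC plates were coated with serum. Among genes of DNA methylation the de novo methyltransferase Dnmt3b was 7.09-fold higher, while Tet2, Dnmt3l and Tet1 were lower and Prdm14 (7.51 FPKM in ESCs) was listed at 0 in EpiSCs. Of the BMP pathway components, 3 of 12 were higher in EpiSCs, Bmp7, Chrd and Acvr1, and 2 lower, Gdf3 and Bmp4 (median 0.70). Bmp7 stood at 0.47 and 7.68 FPKM and Bmp4 at 19.5 and 0.263 FPKM. Of the BMP targets, 5 of 15 were higher, Fst, Bambi, Hey1, Msx1 and Msx2, and 2 lower, Id1 and Tsc22d1 (median 0.19), with intervals apart for Fst alone among these 7. Id1 stood at 70 and 14.1 FPKM, with overlapping intervals.

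**Figure D1:**
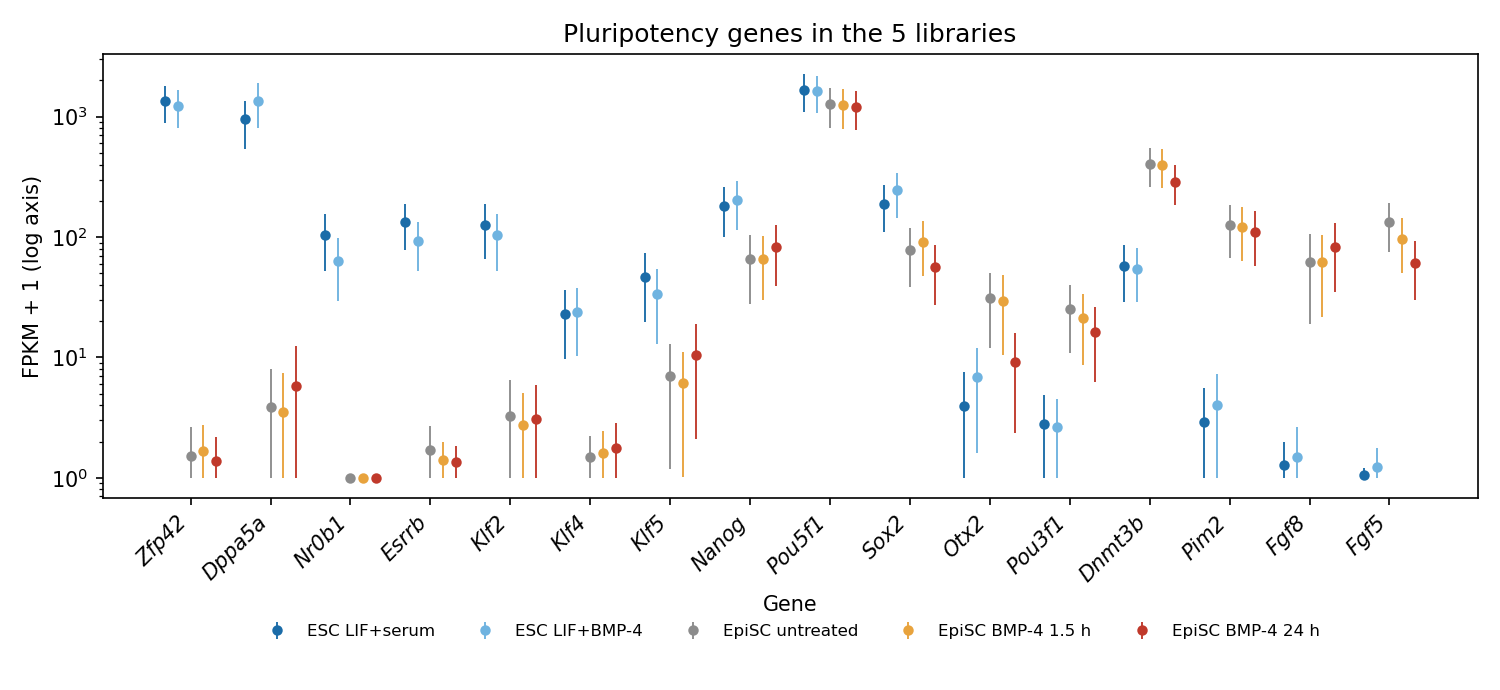
FPKM + 1 on a log axis for 16 pluripotency genes, with 1 point per library, coloured by library, and bars for the deposited intervals. Zfp42 lies at 1336 and 1227 FPKM in the ESC libraries and below 1 FPKM in the EpiSC libraries, Pou5f1 lies between 1208 and 1677 FPKM in all 5 libraries, and Fgf5 lies between 60.2 and 133 FPKM in the EpiSC libraries.

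In number, 1272 genes were higher and 1051 lower in untreated EpiSCs than in ESCs in LIF and serum. Against ESCs in LIF and BMP-4, 1209 were higher and 1104 lower. The intervals were apart for 295 and 313 of these genes in the first comparison and for 263 and 342 in the second. By size, the largest differences against LIF and serum also included the neurofilament gene Nefl (10.8 and 469 FPKM) and the zinc transporter gene Slc39a8 (0.171 and 35.2 FPKM) among higher genes, and the threonine dehydrogenase gene Tdh (226 and 0.618 FPKM) and the small heat shock protein gene Hspb1 (733 and 8.53 FPKM) among lower genes. The sequences of Tdh and Hspb1 match other genes, which leaves their FPKM uncertain. Naive pluripotency genes were again lower in 20 of 20 cases against ESCs in LIF and BMP-4 (median -4.34), and primed epiblast genes higher in 15 of 19 (median 1.74). Sox2 was 3.12-fold and Nanog 3.07-fold lower in EpiSCs than in ESCs in LIF and BMP-4, both with intervals apart. In that second comparison Morc1 (114 and 0.165 FPKM), Manba (127 and 0.867 FPKM) and Mylpf (330 and 3.1 FPKM) were among the lower genes, and Amot (0.307 and 31.2 FPKM) among the higher genes. With all 5 libraries used, 794 genes lay at least 2-fold higher in each EpiSC library than in either ESC library and 728 the other way round, 1522 in total. The other 9 ways to take 2 of the 5 libraries gave at most 26 genes. These low counts were largely fixed in advance and are no test. Each such split puts ESC and EpiSC libraries on the same side, where genes that differ by cell type cannot count.

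ESCs in LIF and BMP-4 were compared with ESCs in LIF and serum, a comparison in which serum was also replaced by basal medium. Of the naive pluripotency genes 0 of 20 were higher and 1 lower (Tfcp2l1, 40.7 and 19.8 FPKM, overlapping intervals), with a median of -0.05, and Pou5f1 stood at 1677 and 1625 FPKM. Of the primed epiblast genes 2 of 19 were higher with BMP-4, Zic2 (0.826 and 8.13 FPKM) and Zic5 (1.85 and 6.08 FPKM, overlapping intervals), and 0 lower, with a median of 0.47 (percentile 100.0 of matched random lists). Klf2 stood at 125 FPKM with serum and 103 with BMP-4, Klf4 at 22.1 and 23.0, and Klf5 at 45.7 and 32.6. Of the BMP targets 2 of 15 were higher with BMP-4 and 1 lower, and 12 lay within 2-fold (median 0.26, percentile 99.5). Id2 was 5.1-fold higher, from 8.98 FPKM (0.19 to 17.8) to 49.9 (18.6 to 81.2), and Dusp9, a phosphatase that acts on ERK, was 2.71-fold higher, with overlapping intervals. Id1 stood at 70 FPKM with serum and 101 with BMP-4, and Id3 at 24.4 and 40.0, both with overlapping intervals. Fst, which encodes the Activin antagonist follistatin, was 2.77-fold lower, also with overlapping intervals.

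Several metabolic lists were also compared between the ESC libraries. Of the cholesterol and fatty acid synthesis genes, 10 of 25 were higher with BMP-4 and 0 lower (median 0.91, percentile 100.0 of matched random lists), including the desaturases Scd1 (12.5 and 39.7 FPKM) and Scd2 (51.7 and 144 FPKM) and the sterol reductase Dhcr7 (5.54 and 17.2 FPKM). The intervals were apart for Scd2 and overlapped for Scd1 and Dhcr7. Of the glycolysis and hypoxia genes, 5 of 18 were higher (median 0.61, percentile 100.0), led by the mitophagy receptor Bnip3 (1.19 and 22.7 FPKM, with sequence shared with another gene) and triosephosphate isomerase Tpi1 (138 and 416 FPKM). Of the oxidative phosphorylation genes 0 of 19 were higher or lower (median 0.00). The stress genes had a median of -0.74 (percentile 0.0), with 3 of 12 lower and 1 higher. Atf4, the transcription factor of the integrated stress response, was 4.35-fold lower, from 334 FPKM (191 to 476) to 75.9 (32.4 to 120). The p53 response genes had a median of -0.57 (percentile 0.0), with Perp lower (overlapping intervals). Serum and SRF response genes had a median of -0.21 (percentile 2.0), with 2 of 14 lower and 1 higher. Further genes with intervals apart were Igf2bp3, Gpc3, Zic2 and Upp1, all higher with BMP-4, and Nkx6-3, Bex1 and the imprinted growth regulator Grb10, all lower.

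In total 287 genes were higher and 141 lower with BMP-4 than with serum, and the intervals were apart for 18 and 4 of them. The correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.96 between the ESC libraries and 0.86 between ESCs in LIF and serum and untreated EpiSCs. Without a library of ESCs in basal medium and LIF alone, the change of medium and BMP-4 were not separated.

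Treatment of EpiSCs with BMP-4 for 1.5 h was compared with untreated EpiSCs to describe the early response in the primed state. Of the inhibitor of differentiation genes, direct targets of BMP signalling, Id1, Id2 and Id3 were higher. Id4, with a mean below 1 FPKM over the libraries, stood at 0.259 and 0.174 FPKM. Id1 (chromosome 2, 152561987 to 152563146) was 12.3-fold higher, from 14.1 FPKM (0.164 to 28.1) to 184 (87.2 to 282), and Id3 (chromosome 4, 135699737 to 135701307) was 5.25-fold higher, from 28 (5.27 to 50.8) to 151 (68.5 to 234). Id2 was 3.55-fold higher (17.3 and 64.0 FPKM) and the homeobox gene Msx2 2.13-fold higher (1.25 and 3.79 FPKM), with overlapping intervals. Thus 4 of 15 BMP targets were higher and 0 lower, with a list median of 0.60 (percentile 100.0), while Smad7 stood at 20.2 and 25.3 FPKM and Bambi at 6.57 and 6.44 FPKM.

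Foxa2, a transcription factor of definitive endoderm and the node, was 2.81-fold lower after 1.5 h (13.2 and 4.06 FPKM, overlapping intervals). The streak genes had a median of -0.26 (percentile 0.0), though 0 of 15 were 2-fold higher or lower. The naive list (median -0.02), the primed list (median -0.08) and the Nodal and Activin list (median -0.02) each held 0 genes that were higher or lower. The 3 Nodal and Activin targets lower at 24 h, Lefty1 (70 and 35.7 FPKM), Gsc (36.0 and 25.3 FPKM) and Cer1 (35 and 29.1 FPKM), also stood below their untreated values. Those changes were under 2-fold, with overlapping intervals. The 3 genes were picked at 24 h against the same untreated library. A high value in that library would put them low at both times, so their direction at 1.5 h is no sign of an early onset. Pou5f1 stood at 1264 FPKM before and 1242 after 1.5 h, Nanog at 64.7 and 64.8, and Klf2, Klf4 and Klf5 at 1.73, 0.593 and 5.1 FPKM after 1.5 h.

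Altogether 26 genes were higher and 20 lower after 1.5 h, and without small RNAs and predicted genes, an exclusion added after the data were seen, 13 were higher and 6 lower. The intervals were apart for 3 genes, Id1, Id3 and Eif3j1, and Eif3j1 (0.135 and 60.1 FPKM) shares sequence with Eif3j2, named after its values were seen, which stood at 99.5 and 38.2 FPKM.

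After 24 h of BMP-4, 6 of 15 genes of the primitive streak and early mesoderm were higher than in untreated EpiSCs and 2, Gsc and Lhx1, were lower (median 0.76, percentile 100.0). T (Brachyury, a mesoderm transcription factor; chromosome 17, 8627288 to 8635361) was 7.02-fold higher, from 11.9 FPKM (2.78 to 20.9) to 89.2 (44.4 to 134). Cdx2, a posterior and trophoblast transcription factor, was 5.75-fold higher (1.55 and 13.7 FPKM) and Evx1 5.62-fold higher (0.246 and 6.01 FPKM), each with overlapping intervals. Mesp1, a gene of early cardiac mesoderm, was listed at 0 in untreated EpiSCs and stood at 7.32 FPKM (0 to 15.6) after 24 h. Mesp1 and Evx1 pass the mean filter through their 24 h values. The streak count and median, here and against 1.5 h, are thus partly set by the filter. Of 13 posterior streak genes, a list chosen after the data were seen and so no independent evidence, 9 were higher and 0 lower (median 1.37).

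BMP targets were higher in 7 of 15 cases and lower in 0 (median 1.00, percentile 100.0). Id1 stood at 199 FPKM (97.0 to 301), Id3 at 192 (93.2 to 291) and Id2 at 76.0 (32.5 to 120) after 24 h, all with intervals apart from those of untreated EpiSCs. Msx1 was 4.62-fold higher (1.64 and 11.2 FPKM), Msx2 4.39-fold (1.25 and 8.88 FPKM) and the inhibitory Smad6 2.35-fold (0.85 and 3.35 FPKM), each with overlapping intervals. Gata2, at 0.495 and 2.00 FPKM with overlapping intervals, completed the 7, and it passes the mean filter only with its 24 h value. Of the Wnt targets, 3 of 8 were higher, T, Axin2 (7.31 and 20.4 FPKM) and Sp5 (9.25 and 20.6 FPKM), with a median of 0.94 and overlapping intervals for Axin2 and Sp5. Of the primordial germ cell genes, Nanos3 alone of 11 was at least 2-fold higher (0.721 and 5.7 FPKM), with overlapping intervals. Alox15, a lipoxygenase gene, was 4.52-fold higher with intervals apart (13.9 and 66.3 FPKM).

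Of the Nodal and Activin targets 3 of 14 were lower after 24 h and 0 higher (median 0.12), and of the endoderm genes 2 of 13 were lower, Cer1 and Foxa2, and 0 higher (median -0.22). Cer1 (chromosome 4, 82527655 to 82531055) was 15.6-fold lower, from 35 FPKM (13.2 to 56.8) to 1.31 (0 to 3.1), Lefty1 (chromosome 1, 182865170 to 182868532) 7.53-fold lower, from 70 (31.1 to 109) to 8.42 (0.916 to 15.9), and the organizer gene Gsc (chromosome 12, 105709419 to 105711446) 6.63-fold lower, from 36.0 (11.2 to 60.8) to 4.58 (0 to 9.88). These 3 were the lower genes with intervals apart. Foxa2 was 4.98-fold lower (13.2 and 1.86 FPKM) and Lhx1 3.13-fold lower (13.2 and 3.53 FPKM), with overlapping intervals. Of 11 anterior streak and organizer genes, likewise listed after the data were seen, 7 were lower and 0 higher (median -1.65). Of the primed epiblast genes, 3 of 19 were lower, Otx2 (30.1 and 8.21 FPKM), Fgf5 (133 and 60.2 FPKM) and Sox3 (4.55 and 1.6 FPKM), with a list median of -0.19. The BMP antagonist gene Chrd was 2.56-fold lower. The intervals overlapped for Otx2, Fgf5, Sox3 and Chrd. Pou5f1 stood at 1208 FPKM after 24 h, Nanog at 81.4, Sox2 at 55.5, Klf2 at 2.06, Klf4 at 0.78 and Klf5 at 9.52 FPKM. The naive list had a median of 0.09, with Tbx3 higher (0.0636 and 1.86 FPKM, overlapping intervals).

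**Figure D2:**
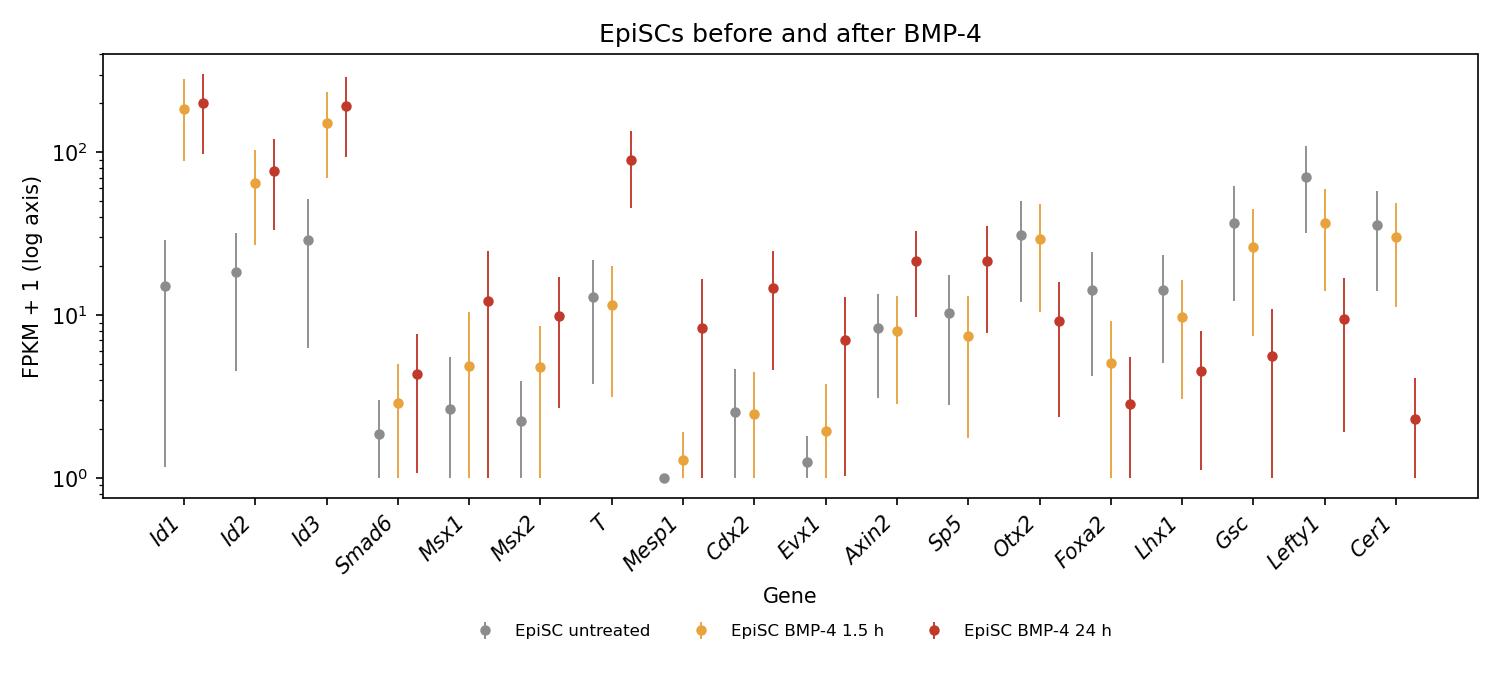
FPKM + 1 on a log axis for 18 genes in the 3 EpiSC libraries, with 1 point per library, coloured by time of BMP-4, and bars for the deposited intervals. Id1 stands at 184 FPKM after 1.5 h and 199 after 24 h, while T stands at 10.6 and 89.2 and Cer1 at 29.1 and 1.31.

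After 24 h 72 genes were higher and 58 lower than in untreated EpiSCs, with intervals apart for 6 and 3 of them. The counts without small RNAs and predicted genes were 54 and 39. Pisd-ps1, 1 of the 6 (0.0467 and 7.1 FPKM), matches the related pseudogene Pisd-ps2 in sequence. The sum of Pisd-ps1 with Pisd-ps3, which was not among its matches, was added after the values were seen. That sum was 7.44 FPKM before and 7.39 after.

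The times of BMP-4 were compared directly. Id genes stood close together at both times: Id1 at 184 and 199 FPKM, Id2 at 64.0 and 76.0 and Id3 at 151 and 192. The streak and mesoderm genes were higher at 24 h than at 1.5 h in 7 of 15 cases and lower in 2 (median 0.99, percentile 100.0), with T 7.77-fold and Cdx2 5.92-fold higher. Msx1 was 2.51-fold, Msx2 2.06-fold and Fst 2.61-fold higher at 24 h. Cer1 was 13-fold lower, Gsc 4.7-fold and Lefty1 3.9-fold lower. Of these, T, Cdx2 and Cer1 had intervals apart. In number 67 genes were higher and 47 lower, with intervals apart for 4 and 2. Without small RNAs and predicted genes 51 were higher and 31 lower.

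The genes higher at both times numbered 14, and the genes lower at both times numbered 13. Independent lists of these sizes would share 0.17 and 0.105 genes. Id1, Id2, Id3, Msx2, Coch, Isg15 and Msx1os were among the 14, and Foxa2 and Btg3 among the 13, and small RNAs and predicted genes made up the others. Coch, Isg15, Msx1os and Btg3 were named after their values were seen. Both comparisons share the untreated library, and unchanged libraries simulated against it gave 686 genes in the same direction from the deposited intervals and 1.25 from read counting alone, against 27 observed. The simulation from intervals put 1840 and 1870 unchanged genes 2-fold apart at 1.5 h and 24 h, against 46 and 130 observed. Its spread is thus far wider than that of these libraries, and 686 is no yardstick. Read counting leaves out any spread between cultures, so 1.25 may be too low. The covariance of the differences was 0.0593, beside 0.395 and 0.0169 in those simulations, and r was 0.46 beside 0.50 and 0.55. The untreated library could not be split, so the part of the overlap that stems from sharing it was not separated.

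The ESC comparison, in which the medium differed as well as BMP-4, and the EpiSC comparison after 24 h were set side by side by the genes at least 2-fold different in both. Id2 was higher in ESCs in LIF and BMP-4 and in EpiSCs after 24 h, as were Coch, Nlrp9b and Olfm2, which were named after their values were seen. In all, 8 genes were higher in both (1.88 from independent lists) and 8 lower in both (0.743), while 8 were higher in ESCs and lower in EpiSCs (1.51) and 5 the opposite (0.922). Small RNAs and predicted genes made up 4, 5, 3 and 5 of these, in that order. Cholesterol and fatty acid synthesis genes, with a median of 0.91 in the ESC comparison, had a median of -0.23 in EpiSCs after 24 h, where 0 of 25 were 2-fold higher or lower. T and Cer1, both at least 2-fold different in EpiSCs after 24 h, were listed at 0 in ESCs with BMP-4.

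**Figure D3:**
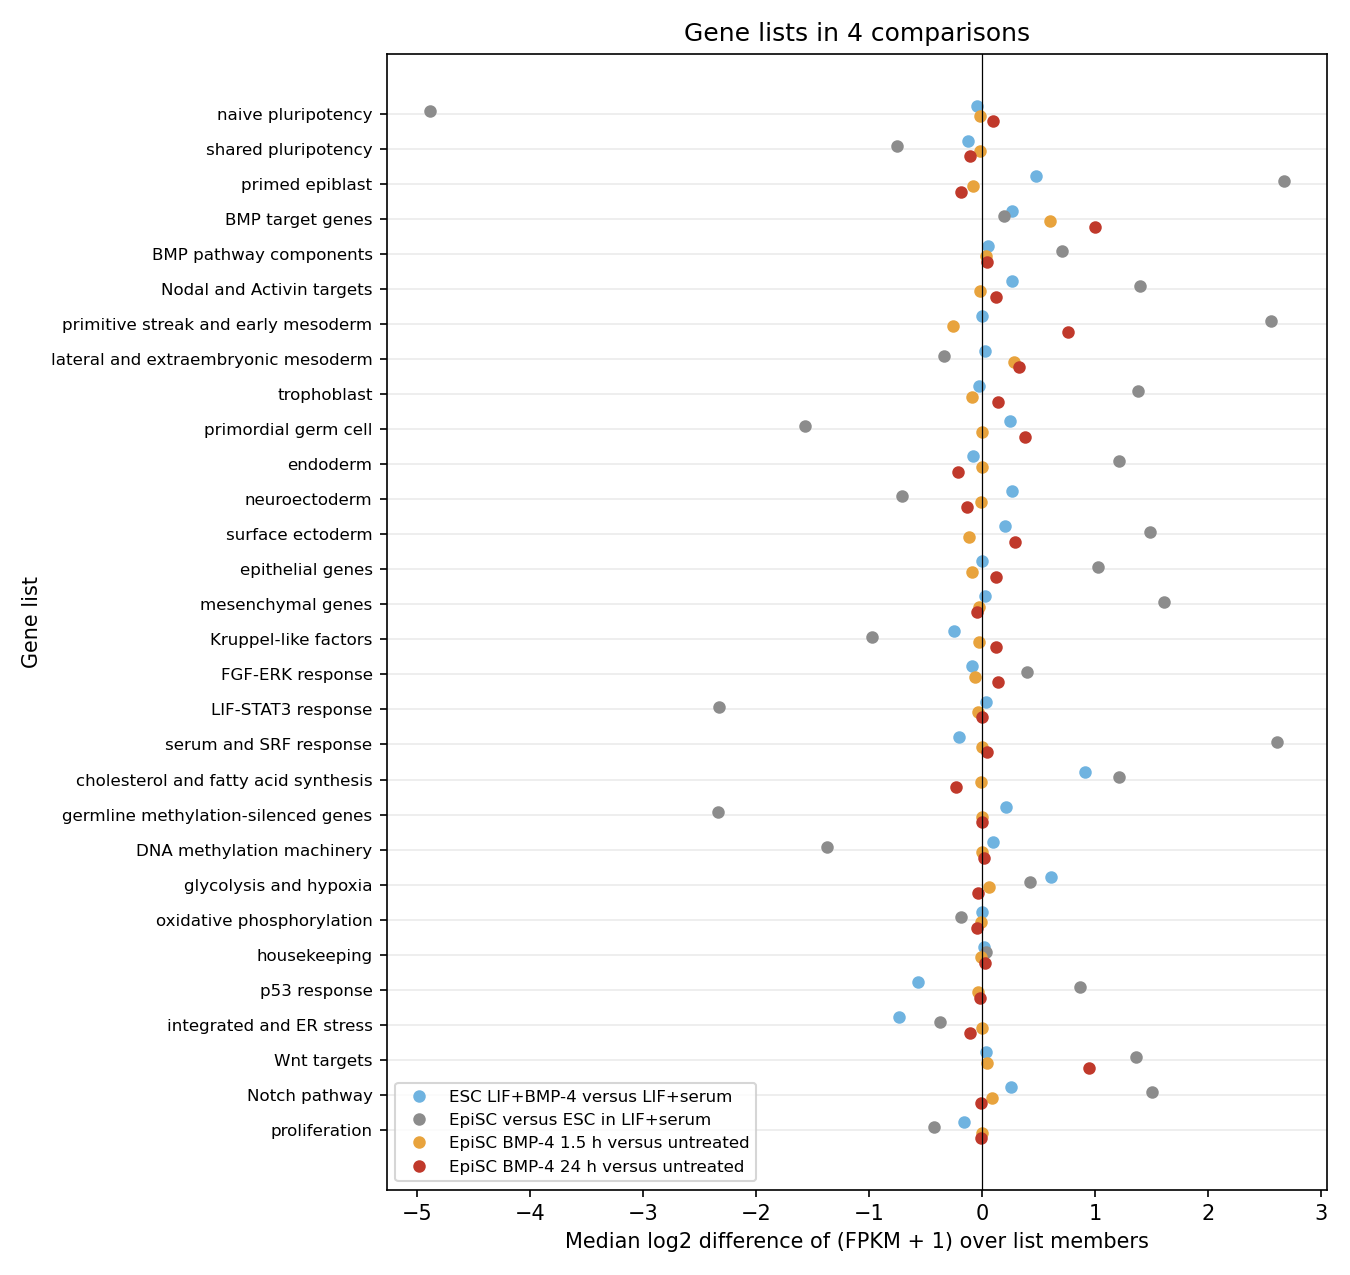
Median log2 difference of FPKM + 1 over the members of 30 gene lists (rows), with 1 point per comparison for 4 comparisons, coloured by comparison. Only lists fixed before the data were examined, with at least 5 members compared, are drawn. Untreated EpiSCs against ESCs in LIF and serum spread from -4.89 for naive pluripotency to 2.67 for primed epiblast. Among the lists drawn, the 24 h comparison has its highest median, 1.00, for BMP targets.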

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

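Of the alternatives, the exclusion of small RNAs and predicted genes was chosen after the data were seen. No named gene at least 2-fold apart turned its direction under either pseudocount or rescaling. No list with a median of at least 1 in size did under either pseudocount or median-ratio rescaling. These outcomes were largely fixed in advance and are no support, because a pseudocount cannot turn a gene and the rescaling factors lay close to 1. The factors ran from 0.992 to 1.023 by median ratio and from 0.966 to 1.057 by upper quartile. Such factors also leave little room for the counts to move. Rescaling by median ratio kept all 16 counts within 1.5 times of those reported, and upper-quartile rescaling or no filter did so for the 14 counts other than the overlaps, for which they were not run. In the order ESC LIF and BMP-4 against serum, EpiSC against ESC in serum, EpiSC against ESC in BMP-4, 1.5 h, 24 h and 24 h against 1.5 h, written as higher and lower, a pseudocount of 5 gave 92 and 60, 517 and 545, 486 and 610, 15 higher, 35 and 30, and 30 and 25. A mean of at least 5 FPKM gave 151 and 91, 709 and 614, 675 and 624, 12 lower at 1.5 h, 34 and 33, and 36 and 31. Requiring intervals apart gave 18 and 4, 295 and 313, 263 and 342, 3 and 0, 6 and 3, and 4 and 2. A pseudocount of 0.1 gave 600 and 280 for the ESC comparison, 69 and 59 at 1.5 h, 165 and 131 at 24 h, and 130 and 108 for 24 h against 1.5 h. Without small RNAs and predicted genes 13 and 6 remained at 1.5 h and 31 lower genes for 24 h against 1.5 h. Genes that part all EpiSC from all ESC libraries numbered 295 higher and 359 lower in EpiSCs at a pseudocount of 5, and 446 and 421 at a mean of at least 5 FPKM. The overlap of 1.5 h and 24 h was 71 at a pseudocount of 0.1, and that of ESCs and EpiSCs at 24 h was 55 at 0.1 and 9 at 5. Higher pseudocounts and filters remove low genes by construction. Of the named-gene differences under alternatives 282 moved beyond the width of their combined intervals, all of them under a pseudocount, and 1706 did not. Of the list medians 7 moved beyond the SD of their members and 533 did not. These labels are descriptive, since no test was run. No paired analysis was possible because each group held 1 library. Summing rows of 1 symbol was not run because symbols were unique, and no library could be left out with 1 per group. Depth limits the genes near 1 FPKM, where the intervals exceed the value itself.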

Other observations

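Each test of an explanation in this part was chosen after the results were seen, some were changed after a first run, and the bounds for the Eif3j genes were set with their values known. Of 14 germline genes known to be silenced by DNA methylation, 7 had a mean of at least 1 FPKM. These were lower in untreated EpiSCs than in ESCs in LIF and serum in 7 of 7 cases (median -2.34). A gene near 0 in EpiSCs passes the filter only through its ESC values, so this count is partly set by the filter. Ddx4 stood at 20.8 and 0.11 FPKM, and Hormad1 and Tex11 at 5.98 and 4.55 FPKM in ESCs while both were listed at 0 in untreated EpiSCs. Primordial germ cell genes were lower in 8 of 11 cases (median -1.57), among them Ifitm3 (260 and 14.1 FPKM) and Alpl (31.7 and 2.72 FPKM). Genes of the p53 response were higher in EpiSCs in 6 of 12 cases and lower in 1 (median 0.86), with the cell cycle inhibitor Cdkn1a at 7.36 and 33.3 FPKM and the apoptosis gene Pmaip1 at 7.32 and 0.115 FPKM. Notch pathway genes were higher in 6 of 8 cases (median 1.50), with Dll3 at 0.278 and 7.02 FPKM. Of 12 fibroblast markers 2 had a mean of at least 1 FPKM, and 1 of these, S100a4, was at least 2-fold higher in untreated EpiSCs (0.749 and 2.59 FPKM, overlapping intervals). The fibroblast collagen genes Col1a2 and Col3a1, picked after their values were seen, reached at most 0.182 and 0.826 FPKM, both in EpiSCs after 24 h.

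Imprinted genes, listed after the data were seen, went both ways between untreated EpiSCs and ESCs in LIF and serum, with 6 of 18 higher and 2 lower (median 0.53). Cdkn1c, a growth inhibitor, stood at 46.5 and 263 FPKM, Snrpn at 44.6 and 227 FPKM and Peg3 at 1.88 and 15.1 FPKM. Peg10 stood at 16.6 FPKM in ESCs with serum and was listed at 0 in all 3 EpiSC libraries, and Mest stood at 11.4 and 0.0862 FPKM. In ESCs, the 2-cell marker Zscan4f, which shares its sequence with related genes, stood at 0.201 FPKM with serum and 5.93 with BMP-4. The beta-glucuronidase gene Gusb, often used as a reference gene, stood at 9.75 and 8.14 FPKM in ESCs and at 0.125 FPKM or less in EpiSCs. Hprt and Gapdh, further reference genes, were picked after their values were seen. Hprt stood between 0.303 and 0.857 FPKM in all 5 libraries, while Gapdh stood between 1474 and 1680. E14 sublines with a defect of Hprt are known, and the labels do not say which subline was used.

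After 1.5 h of BMP-4 24 of the 46 genes at least 2-fold apart were small RNAs, 52.2% against 0.627% of all genes compared, and no explanation of this was tested. The higher Eif3j1 and lower Eif3j2 could be reads moved between these genes, since Eif3j2 matches part of Eif3j1 over its whole length at 99.4% identity and their summed FPKM was 99.7 before and 98.3 after 1.5 h, a log2 difference of -0.02. A response of Id1, Id2, Id3 and Msx2 to BMP-4 remains a hypothesis without a replicate.

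Of the cholesterol and fatty acid synthesis genes 10 of 25 were higher in ESCs in LIF and BMP-4 than in LIF and serum (median 0.91), while the median of all genes compared was -0.02. No rise of the list was seen with BMP-4 in EpiSCs, where the median after 24 h was -0.23 and 22 of 25 members lay below 0. This cannot decide whether BMP-4 acts alike in either cell type. The EpiSCs had no serum in the medium before BMP-4, their list level was already raised, and the ESCs were kept with BMP-4. Removal of serum, which supplies sterols, may account for the difference: untreated EpiSCs, kept without serum in the medium, lay 1.21 above the same ESC library, and 0.36 above ESCs in LIF and BMP-4, with 2 of 25 higher. Cell type differs in each and BMP-4 in the second, so serum and cell state cannot be told apart. An action of BMP-4 in ESCs alone was not tested.

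After 24 h of BMP-4 6 of 15 streak genes, a count partly set by the filter, were higher while Cer1, Lefty1 and Gsc were lower. The lowering was not shared by all Nodal and Activin targets: the median over all 14 members was 0.12 (SD of members 1.46), and 8 of 14 lay above 0. Cer1, Lefty1 and Gsc were taken as the 3 members at least 2-fold lower. Their distance from the median, with Gsc the least lowered at -2.73, was therefore set by that choice and is no test. Some members, such as Fgf8, Eomes and Smad7, are also streak genes or BMP targets, so a lowering of Nodal signalling that these genes escape stays open. Neither an action of BMP-4 on these genes nor a difference between culture dishes was tested, because each time had 1 library.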
